A study of Mus musculus with 12 samples.

How the data were processed

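The series holds 12 samples of mouse tail tip fibroblasts: 6 RNA-seq libraries, 2 for each Hotair genotype, and 6 ChIP-seq libraries. RNA was selected for poly(A) tails and libraries were made by a dUTP protocol, which marks the strand, per the labels' protocols. Reads were aligned with TopHat to mm9, per the submitters' processing notes. Whether counting used the strand is not given in the sources used here, so reads of Hotair, which lies antisense to Hoxc11, are reported as counted. The ChIP-seq libraries are not analysed here.

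The deposited table gives 1 value per gene symbol and RNA library, for 24132 symbols, with no unit in its header. The values were identified as RPKM from the deposited numbers themselves. A step per library, the worth of 1 read, was found from low values times whole gene lengths. These steps gave whole totals of aligned bases (largest residual 5.2e-06) when a read was taken as 74 bases. Of the values above 0, 6.87% lay within 0.01 reads of a whole multiple of the step. A gene length that made the aligned bases whole in every library (tolerance 0.002 bases) was found for 18884 of the 18888 genes above 0. Each value is therefore aligned bases over exons, scaled to the gene's length and the library's total, and can hold fractions of a read. The annotation version and any filter applied by the authors are not given in the sources used here. Values came from coverage tracks and genes were collapsed to 1 row per symbol, per the file headers and the name of the table.

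Recovered depths were 29.6M and 27.9M read equivalents in the wild-type libraries, 33.2M and 31.2M in the heterozygous and 48.1M and 46.0M in the knockout libraries, 1.64 times more in knockout than in wild type. Between 47.5% and 48.8% of them fell in gene rows. The floor given for a value of 0 corresponds to 3 read equivalents.

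Replicate libraries were compared with counting noise over genes with more than 20 read equivalents. The typical gene varied between replicates by less than counting noise (robust variance 0.805, 0.861 and 0.861 of the counting variance in wild type, heterozygous and knockout), while 41, 45 and 52 genes differed by over 4 SD. First libraries of different genotypes differed far more (5.19 for wild type against heterozygous, 12.3 for wild type against knockout, 6.93 for heterozygous against knockout). Summed over all genes the replicates did differ by more than counting noise (mean squared z of 1.23, 1.36 and 1.66), so they were kept as 2 libraries. Nothing in the labels says that they came from separate animals or cultures. The p-values therefore measure only the spread between these libraries, which may be technical, and compare these cell preparations rather than genotypes in general.

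Values were taken as log2(RPKM + 1), for genes at 1 RPKM or more in at least 2 of the 6 libraries (10897 genes). Differences on this scale understate the change of low genes. A model with 3 group means was fitted with limma 3.58.1 in R 4.3.3 (lmFit, eBayes with an intensity trend, 3 residual degrees of freedom), two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. A second model took the number of disrupted alleles (0, 1 or 2) as a slope. As a description that needs no estimate of spread, genes were counted whose means lay at least 1 apart on the log2 scale with no overlap of replicates. Errors are SD between the 2 libraries for RPKM and SE of the model for log2 differences. On simulated data for knockout against wild type (10362 genes, 50 changed at each size), the fit recovered 56% of genes changed 1.25-fold, 96% at 1.5-fold, 98% at 2-fold and 100% at 4-fold, and called 8 of 10162 unchanged genes. Changed genes were drawn only from those with a wild-type mean of at least 2 RPKM, so recovery of lower genes was not measured. The simulation held counting noise and a small added spread between libraries, without differences between cell preparations. It therefore does not bear on calls that such differences would cause.

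Gene lists (40 lists, 738 genes, of which 735 matched a symbol) and all main tests were fixed before the data were examined. Lists with at least 5 genes passing the filter (29 lists) were tested with camera (correlation between genes set to 0.01), with an estimated correlation as the alternative. By fry, which tests whether the genes of a list move on balance in 1 direction, 25, 26 and 24 lists changed in knockout against wild type, heterozygous against wild type and knockout against heterozygous. The rule for named genes was Hotair first, then for each comparison the 10 largest rises and 10 largest falls among called genes with no overlap of replicates, then Hoxc11, Hoxc12, measured HoxD genes, up to 4 members of each list with the smallest p in knockout against wild type, and sex-linked genes per library. Plagl1, Cd14, Laptm5, Psph, Psat1, Atf4, Scx, Tnmd, Atp6v0d2, Ctss and Mpeg1 are named outside it, chosen after their values were seen. Chromosomes were taken by symbol from a RefSeq table of GRCm38 (21496 of the symbols matched) and no coordinates are given, since the files use mm9.

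Alternatives were the pseudocount, the filter, quantile normalization, median scaling, the variance model, the replicate number as a block, each library left out in turn, the compared groups alone, a 2-fold threshold and list membership. Limma's voom on the recovered read equivalents, autosomal genes alone, the slope without heterozygous libraries, and 1 wild-type library for each comparison were added after seeing the data.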

Results

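Polyadenylated RNA was sequenced from tail tip fibroblasts of newborn mice, connective tissue cells grown out of the tail, on a background backcrossed to C57BL6. The cells carried 0, 1 or 2 disrupted copies of Hotair, and each genotype (wild type, heterozygous, knockout) was represented by 2 libraries. Hotair is a long noncoding RNA transcribed from the HoxC cluster between Hoxc11 and Hoxc12, and it has been studied as a partner of the Polycomb repressive complex 2 and of the LSD1-CoREST complex. The series asks how its disruption changes expression, with homeotic and imprinted genes in view. Each wild-type or heterozygous library held between 27.9M and 33.2M aligned read equivalents, and the knockout libraries held 48.1M and 46.0M. The ChIP-seq samples of the series (6 libraries) are not analysed here.

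Hotair itself was low in every library. It stood at 0.247 and 0.183 RPKM in the wild-type libraries and at 0.213 and 0.172 RPKM in the heterozygous ones, which corresponds to between 5.7 and 8.1 reads per library. Both knockout libraries were at 0. A count of 3 over the 94.1M read equivalents of the knockout group gives a floor of 0.0287 RPKM. The wild-type mean (0.215 ± 0.0448 RPKM, SD, n = 2) lay 7.5-fold above that floor and the heterozygous mean (0.193 ± 0.0288) 6.72-fold. The floor allows for counting error in the knockout value of 0 only. The wild-type and heterozygous means rest on few reads and were taken as exact, so the true ratios to knockout could be lower. A difference between heterozygous and wild type was not detectable at this depth, and the gene lay below the 1 RPKM filter of the test.

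In knockout against wild-type cells, the 10 largest rises included Thbs4, Acp5, Mgp, Prg4 and Lyz2. Thbs4, a thrombospondin of tendon matrix, went from 2.26 ± 0.249 to 64.8 ± 1.79 RPKM (SD, n = 2 libraries per genotype), a log2 difference of 4.34 ± 0.06 (SE). Acp5, the tartrate-resistant acid phosphatase of osteoclasts and macrophages, rose from 0.695 ± 0.0302 to 23.7 ± 0.448 RPKM, and Lyz2, the lysozyme of myeloid cells, from 3.13 ± 0.0973 to 23.7 ± 0.186. Mgp, an inhibitor of calcification, rose from 7.09 ± 0.543 to 83.9 ± 2.47 RPKM, and Prg4, the joint lubricant lubricin, from 2.74 ± 0.135 to 34.6 ± 1.13. Among the largest falls, Phgdh, which catalyses the first step of serine synthesis, dropped from 275 ± 0.74 to 80 ± 2.43 RPKM.

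Further rises in this group were those of Dlk1, an imprinted membrane protein related to Notch ligands (log2 difference 2.95 ± 0.05), Igfbp3, a carrier of insulin-like growth factors (2.69 ± 0.03), and the matrix protein gene Abi3bp (2.63 ± 0.07). Falls were led by Slfn2, a Schlafen family gene (-2.09 ± 0.08), followed by 1500015A07Rik (-1.86 ± 0.07), the deubiquitinase gene Uchl1 (-1.82 ± 0.04), the predicted gene Gm8096 (-1.74 ± 0.03), the crosslinking enzyme gene Tgm2 (-1.70 ± 0.06), Ankrd1 (-1.70 ± 0.05) and Lce1h, of the cornified envelope (-1.65 ± 0.09). Values of Hist1h4m (-1.61 ± 0.08) and 3000002C10Rik are treated as uncertain, since histone genes and Gapdh-like copies can share reads, which was not tested. The latter ranged widely between replicates, with 15.9 ± 19.6 RPKM in knockout. Gm8096 stood at 66.4, 32.8 and 19.2 RPKM in wild type, heterozygous and knockout, in nearly the same proportions as Phgdh (275, 133 and 80 RPKM). Whether these rows share reads was not tested, so the fall of Gm8096 may not be separate from that of Phgdh. Mir5109 (3.54 ± 0.13) and Mir704 (-1.84 ± 0.60) are short rows that can take reads from longer transcripts, and the call of Mir704 (adjusted p = 0.0279) was lost in 7 of the alternative fits.

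Counted over all 10897 genes tested, 279 genes lay at least 2-fold apart with no overlap of the replicates, 200 higher and 79 lower in knockout. Chance alone separates 33.3% of genes when 2 libraries meet 2. limma, with Benjamini-Hochberg adjustment, called 7324 genes (4421 higher, 2903 lower), of which 278 changed at least 2-fold. Of the 7324 calls, 60.4% were higher, against 46.7% after quantile normalization and 50% after median scaling, and 48.2% (2291 higher, 2463 lower) with a filter at 5 RPKM, so the balance of directions depended on scaling and on the filter. The median log2 difference went from 0.23 for genes under 3 RPKM to -0.10 for genes over 100 RPKM. The 2-fold count rests on the pseudocount, with 679 genes at 0.1 and 86 at 5.

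Imprinted genes, expressed from 1 parental copy and named in the title of the series, moved in both directions. Of 44 measured, 20 rose, 15 fell and 9 did not pass the test (21 and 15 when adjusted over the list alone), and all 6 that changed at least 2-fold rose. Of all 10897 genes tested, 67.2% were called (4421 higher, 2903 lower), and 199 of the 278 that changed at least 2-fold rose. Counts of list members in knockout against wild type, here and below, are to be read against these shares. Dlk1 stood at 1.55 ± 0.136, 3.55 ± 0.0351 and 18.8 ± 0.0687 RPKM in wild type, heterozygous and knockout (SD, n = 2 each). H19, a maternally expressed noncoding RNA that restrains growth, stood at 5.89 ± 0.0362, 10.1 ± 0.4 and 30.6 ± 0.586 RPKM. Dio3, which inactivates thyroid hormone and lies in the same imprinted domain as Dlk1, stood at 20.3 ± 0.122, 82.2 ± 0.906 and 83.4 ± 1.73 RPKM. Mest rose by a log2 difference of 1.68 ± 0.08, Plagl1 by 1.17 ± 0.06 and Dcn, a collagen-binding proteoglycan imprinted in placenta, by 1.11 ± 0.06. Meg3, the maternal noncoding RNA of the Dlk1 domain, rose by 0.85 ± 0.04, and Impact by 0.82 ± 0.04.

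As one list, imprinted genes had a median log2 difference of 0.06, and camera found no shift against other genes (p = 0.643; p = 0.618 with an estimated correlation). Paternally expressed genes (18 measured, 11 higher and 4 lower, the same counts adjusted over the list alone) had a median of 0.25 and an adjusted p of 0.126 (median 0.03, adjusted p = 0.283 after quantile normalization). Maternally expressed genes (20 measured, 7 higher and 8 lower; 8 and 8 adjusted over the list alone) had a median of -0.06, and their mean of 0.20 had the opposite sign. Their adjusted p was 0.816. The remaining 6 genes, with bias by isoform or tissue, gave 2 higher and 3 lower with an adjusted p of 0.429. The sign of the combined median was lost after quantile normalization (-0.006) and with a filter at 5 RPKM (-0.047), and the median was 0.13 without the first and 0.10 without the second wild-type library.

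**Figure D1:**
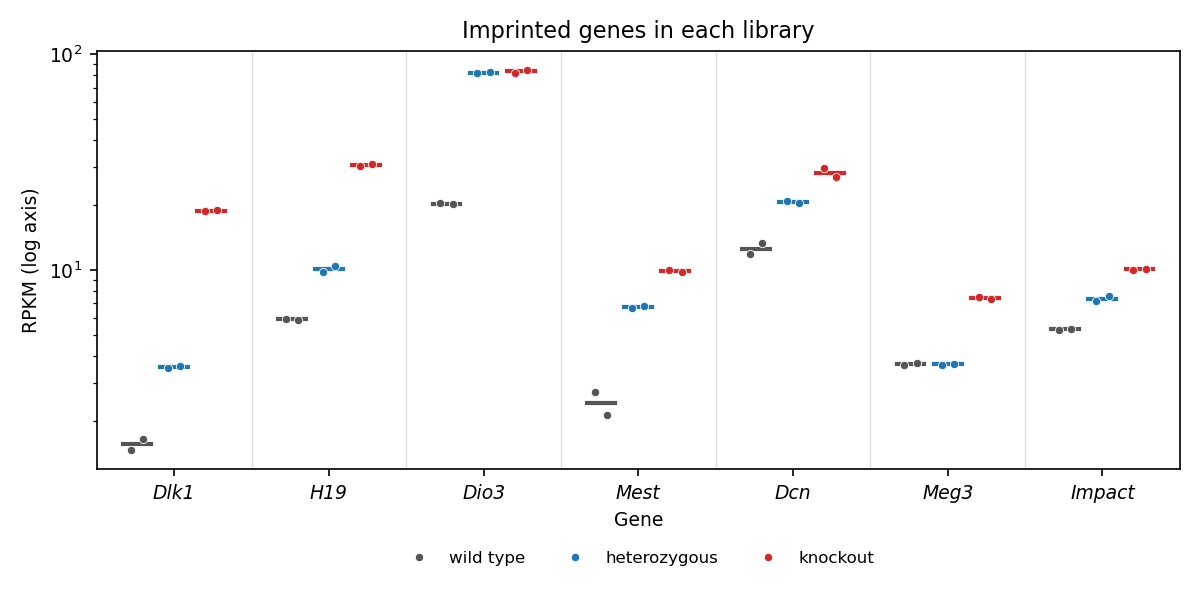
RPKM of 7 imprinted genes (x axis) on a log axis, with 1 point per library, 2 per genotype, and a bar at the mean of each genotype. Dlk1 and H19 increase from wild type over heterozygous to knockout, Dio3 is as high in heterozygous (82.2 RPKM) as in knockout (83.4 RPKM), and Meg3 is higher in knockout (7.40 RPKM) than in the other genotypes.

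Hox genes, which encode position along the body axis, changed by less than 2-fold on the log2(RPKM + 1) scale, although the RPKM ratio of Hoxa13 was 3.13. Of 19 measured, 11 rose and 3 fell (the same counts adjusted over the list alone). The largest were Hoxa13, which rose from 0.623 ± 0.187 to 1.95 ± 0.0371 RPKM (SD, n = 2), and Hoxb13, from 19.6 ± 0.16 to 32.6 ± 1.73. Both belong to the posterior end of their clusters. Hoxa11 rose by 0.33 ± 0.05 and Hoxb9 by 0.29 ± 0.04 on the log2 scale. Next to Hotair, Hoxc11 was at 3.19 ± 0.38 RPKM in wild type and 3.05 ± 0.105 in knockout (log2 difference -0.05 ± 0.07, adjusted p = 0.569; -0.24 with an adjusted p of 0.0179 after quantile normalization), and Hoxc12 fell by 0.22 ± 0.08 (adjusted p = 0.0366), a call lost in 4 alternative fits. HoxD genes were barely expressed: Hoxd8 was the 1 member that passed the filter, at 0.375 ± 0.0015, 1.06 ± 0.0342 and 0.575 ± 0.133 RPKM in wild type, heterozygous and knockout. Its difference between knockout and wild type (0.19 ± 0.07, adjusted p = 0.0431) turned to -0.12 after quantile normalization, and the call was lost in 8 further fits.

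The median log2 difference of the Hox list was 0.18, with a camera p of 0.102 (p = 0.174 with an estimated correlation). It passed the threshold of 0.05 without a filter on low values (median 0.12, camera p of 0.0308), with a filter at 5 RPKM (median 0.31, camera p of 0.0489) and when HoxC genes were left out (median 0.33, camera p of 0.0276). After quantile normalization the median was 0.04 (camera p of 0.481), and with a pseudocount of 5 or 0.1 it was 0.10 or 0.30 (camera p of 0.105 and 0.101). HoxB genes gave 7 higher and 1 lower of 9 (adjusted p = 0.171) and HoxC genes 1 higher and 2 lower of 6 (adjusted p = 0.822). Of 25 measured genes near Hotair on chromosome 15 outside HoxC, 9 rose and 7 fell (adjusted p = 0.822); Hnrnpa1, a splicing factor, rose by 0.79 ± 0.02 and Itga5, the fibronectin receptor subunit, fell by 0.73 ± 0.02.

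Across 29 lists fixed beforehand with at least 5 measured genes, camera called 8 in knockout against wild type, 5 upward and 3 downward. None of the 8 held with an estimated correlation between genes (smallest adjusted p = 0.362). The set of called lists depended on scaling: after quantile normalization camera also called ribosomal protein genes (adjusted p = 0.00728, against 0.126 as reported). Cell cycle genes rose in 25 of 26 cases (25 adjusted over the list alone; median 0.40, adjusted p = 7.38e-05; adjusted p = 0.362 with an estimated correlation). After quantile normalization the median of the cell cycle list was 0.24, still called by camera (adjusted p = 0.000109). Top2a, a topoisomerase of dividing cells, went from 1.69 ± 0.128 to 4.76 ± 0.206 RPKM, and the proliferation marker Mki67 from 0.209 ± 0.00117 to 1.41 ± 0.0186 (SD, n = 2). Myofibroblast and smooth muscle genes fell in 10 of 12 cases, with 1 rise (the same counts adjusted over the list alone), a median of -0.46 and an adjusted p of 2.28e-05 (adjusted p = 0.363 with an estimated correlation). Acta2, the smooth muscle actin of contractile fibroblasts, dropped from 1974 ± 3.63 to 1132 ± 6.43 RPKM, and the related actin Actg2 from 370 ± 3.97 to 163 ± 2.45.

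Macrophage and leukocyte markers rose at least 2-fold in 7 of 8 measured cases (7 adjusted over the list alone; median 1.84, adjusted p = 0.00121; adjusted p = 0.362 with an estimated correlation). Besides Lyz2, the lysosomal protein gene Cd68 rose from 0.929 ± 0.157 to 7.54 ± 0.0972 RPKM, Lyz1 from 0.76 ± 0.122 to 5.63 ± 0.236 and Tyrobp, a signalling adaptor of myeloid cells, from 0.0888 ± 0.126 to 3.64 ± 0.119. Lyz1 (0.76, 0.363 and 5.63 RPKM in wild type, heterozygous and knockout) kept a similar proportion to Lyz2 (3.13, 1.23 and 23.7 RPKM). These lysozyme rows may share reads, which was not tested, and so may not count as separate members. The filter was met by 8 of 17 list members, of which 4 (Cd68, Lyz2, Cd14 and Laptm5) would pass without the knockout values; 3 of these rose at least 2-fold. Of the 9 members under the filter, 7 were higher in both knockout libraries than in all others. Inflammatory cytokines and chemokines gave 11 of 14 higher and 1 lower (the same counts adjusted over the list alone; median 0.42, adjusted p = 0.0147; adjusted p = 0.362 with an estimated correlation). Members included Mmp9, a gelatinase also made by osteoclasts (2.29 ± 0.06), the neutrophil chemokine Cxcl5 (1.72 ± 0.05) and the interleukin 33 receptor Il1rl1 (1.09 ± 0.02). Schwann cell and neural markers moved the other way: 6 of 8 fell and 0 rose, also adjusted over the list alone (median -0.31, adjusted p = 0.00478; adjusted p = 0.362 with an estimated correlation). After quantile normalization the median of the Schwann cell and neural list was -0.53 (camera adjusted p = 0.00251). Ngfr, the low-affinity neurotrophin receptor, dropped from 20.5 ± 0.641 to 11.1 ± 0.279 RPKM and Sox10, a regulator of neural crest, from 3.44 ± 0.333 to 2.06 ± 0.06.

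Of the LSD1-CoREST-REST list, 8 of 9 members rose and 0 fell, also adjusted over the list alone (median 0.42, adjusted p = 0.0405; adjusted p = 0.363 with an estimated correlation). Rest, a repressor of neuronal genes, rose by 0.45 ± 0.04 and its corepressor Rcor1 by 0.42 ± 0.04. Protocadherin and adhesion genes rose in 13 of 17 cases with 1 fall (the same adjusted over the list alone; median 0.35, adjusted p = 0.0158; adjusted p = 0.462 with an estimated correlation), with Pcdh7 at 1.17 ± 0.04 and Pcdh19 at 0.60 ± 0.04. Cell cycle inhibitors and senescence genes gave 7 falls and 3 rises among 10 (the same adjusted over the list alone; median -0.38, mean -0.03, adjusted p = 0.0319; adjusted p = 0.462 with an estimated correlation). Cdkn2a, which encodes cell cycle inhibitors, dropped from 83.7 ± 0.0176 to 51.3 ± 0.168 RPKM, while Igfbp3 of the same list rose. That list was not called after quantile normalization (adjusted p = 0.107) or median scaling (adjusted p = 0.0621).

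Of the lists that were not called, Polycomb repressive complex 2 had 7 of 10 members higher and 0 lower, also adjusted over the list alone (adjusted p = 0.144), with Suz12 at 0.62 ± 0.05, Aebp2 at 0.59 ± 0.04 and the methyltransferase gene Ezh2 at 0.41 ± 0.06. Patterning regulators split into 11 higher and 8 lower of 25, the same adjusted over the list alone (adjusted p = 0.812). Those that rose included Zic1 (1.11 ± 0.07), Prrx2 (1.06 ± 0.03) and Tbx15 (0.86 ± 0.06), all transcription factors of skeleton, muscle or skin patterning. Matrix genes split into 15 higher and 16 lower of 32, the same adjusted over the list alone (adjusted p = 0.822). Lox, which crosslinks collagen, rose from 201 ± 3.29 to 435 ± 0.117 RPKM and Fmod, a collagen-binding proteoglycan, from 3.32 ± 0.157 to 17.4 ± 0.0406, whereas Tnc, the glycoprotein tenascin C, dropped from 403 ± 4.82 to 201 ± 0.13.

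**Figure D2:**
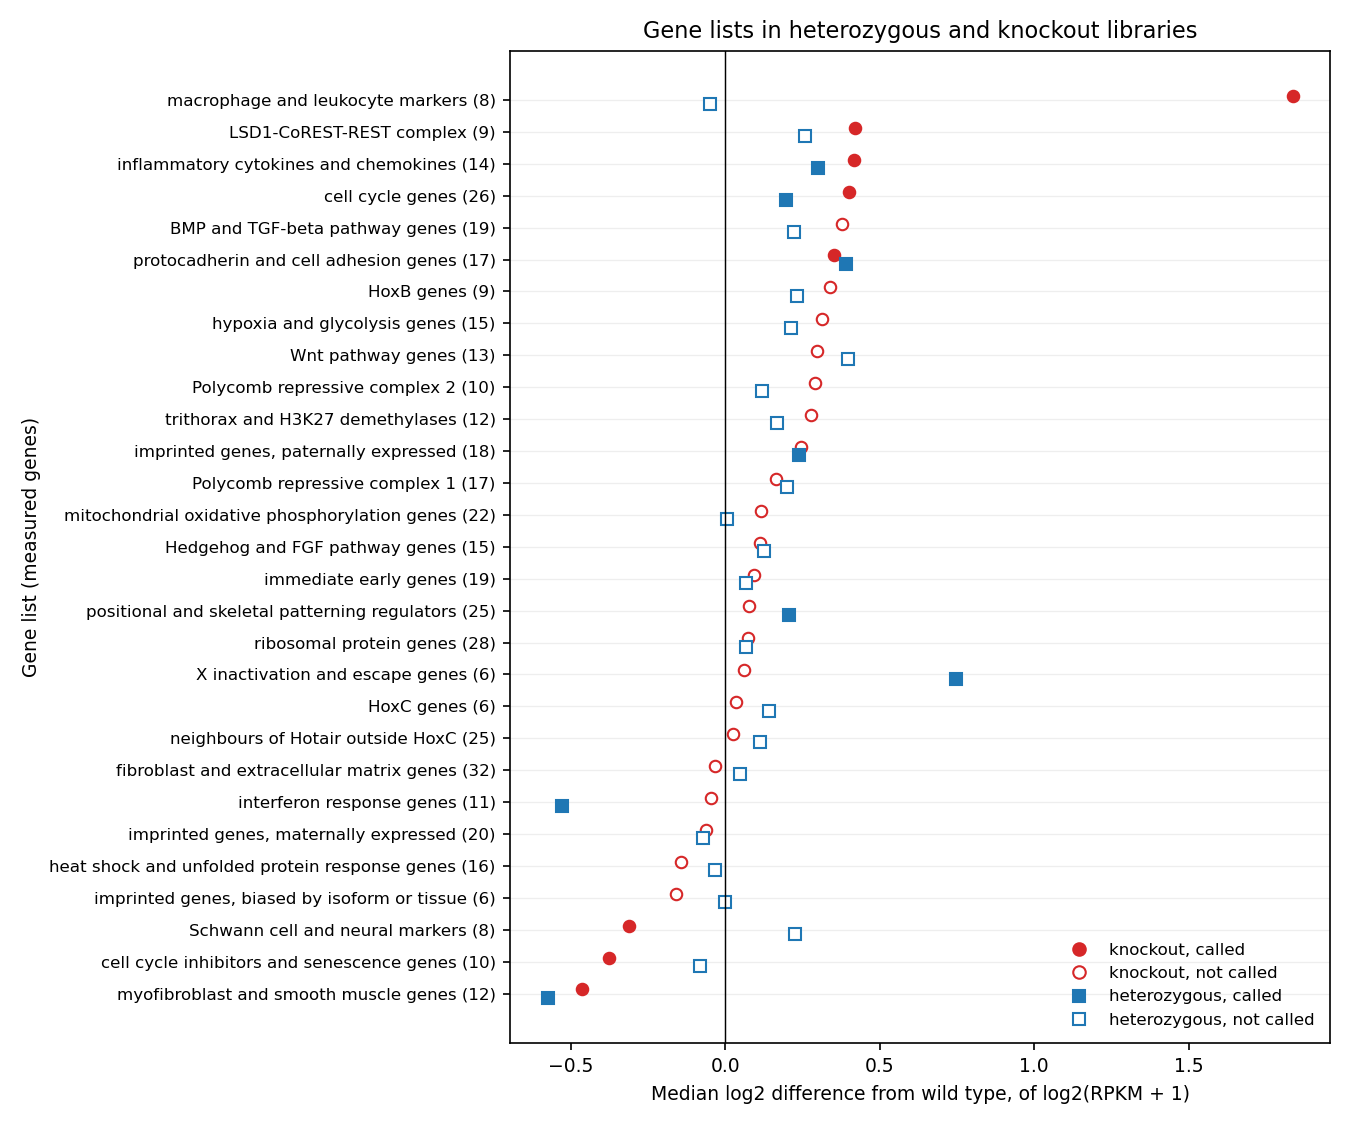
Median log2 difference from wild type (x axis) for each of 29 gene lists (y axis, measured genes in brackets), knockout as red circles and heterozygous as blue squares; filled symbols mark lists called by camera at an adjusted p under 0.05. Macrophage markers lie at 1.84 in knockout and at -0.05 in heterozygous, and myofibroblast genes lie below 0 in both.

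Heterozygous cells shared many of these differences from wild type. Igfbp3 rose from 4.87 ± 0.084 to 34.7 ± 0.02 RPKM (SD, n = 2), Dio3 from 20.3 ± 0.122 to 82.2 ± 0.906, Mgp from 7.09 ± 0.543 to 28.1 ± 2.53, Prelp, a proteoglycan of cartilage and basement membrane, from 3.19 ± 0.418 to 14.7 ± 0.671, and Rab3b, a vesicle GTPase, from 0.405 ± 0.00437 to 4.04 ± 0.234. Uchl1 dropped from 30 ± 0.285 to 7.20 ± 0.242 RPKM, Tgm2 from 15.7 ± 0.412 to 3.56 ± 0.347 and Slfn2 from 7.25 ± 0.758 to 0.951 ± 0.113. Bst2, an antiviral membrane protein induced by interferon, dropped from 32.3 ± 0.0135 to 10.4 ± 1.04 RPKM.

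The remaining large rises were in Xist (2.41 ± 0.05), Cxcl5 (1.65 ± 0.05) and the uncertain rows Mir5109, Mir762 and 3000002C10Rik. Lce1h (-2.16 ± 0.09), Lce1i (-2.04 ± 0.11), 1500015A07Rik (-1.81 ± 0.07), Ifi27l2a (-1.69 ± 0.26), Sprr2k (-1.56 ± 0.11) and Apol10b (-1.55 ± 0.07) completed the largest falls. limma called 5729 genes, 3865 higher and 1864 lower, and 129 of them changed at least 2-fold (84 higher, 45 lower). Higher calls made up 67.5%, against 51.1% after quantile normalization and 51.1% after median scaling.

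Camera called 8 lists in heterozygous against wild type, 6 upward and 2 downward, and none held with an estimated correlation (smallest adjusted p = 0.241). The set of called lists depended on scaling. After quantile normalization camera also called matrix genes (adjusted p = 0.00398, against 0.836 as reported) and LSD1-CoREST-REST genes (0.0243). Hypoxia and glycolysis genes (0.00188), BMP and TGF-beta pathway genes (0.0115) and ribosomal protein genes (0.000835) were then called too. Myofibroblast and smooth muscle genes fell in 12 of 12 cases, also adjusted over the list alone (median -0.57, adjusted p = 4.22e-12; adjusted p = 0.241 with an estimated correlation), with Acta2 at 1021 ± 3.63 RPKM against 1974 ± 3.63 in wild type (SD, n = 2). Interferon response genes fell in 9 of 11 cases, also adjusted over the list alone (median -0.53, adjusted p = 6.65e-07; adjusted p = 0.241 with an estimated correlation); Isg15, a ubiquitin-like protein, fell by 1.42 ± 0.05 and Oas1a, a sensor of double-stranded RNA, by 1.41 ± 0.07. Patterning regulators rose in 17 of 25 cases and none fell (19 higher adjusted over the list alone; adjusted p = 0.00353; adjusted p = 0.241 with an estimated correlation). Paternally expressed imprinted genes gave 11 higher and 3 lower of 18 (13 and 3 adjusted over the list alone). Their median was 0.24, with an adjusted p of 0.042 by camera (adjusted p = 0.298 with an estimated correlation). After quantile normalization the median was 0.13 (adjusted p = 0.0367). Mest rose by 1.18 ± 0.08 and Dlk1 by 0.83 ± 0.05 on the log2 scale.

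Cell cycle genes rose in 15 of 26 cases, also adjusted over the list alone (adjusted p = 0.0216; adjusted p = 0.253 with an estimated correlation; 0.0698 after quantile normalization). Cytokines rose in 10 of 14 cases with 1 fall (11 and 1 adjusted over the list alone; adjusted p = 0.00798; adjusted p = 0.251 with an estimated correlation), and protocadherin and adhesion genes in 12 of 17 with 1 fall, also adjusted over the list alone (adjusted p = 0.0125; adjusted p = 0.36 with an estimated correlation). X inactivation and escape genes rose in 6 of 6 cases, also adjusted over the list alone (median 0.75, adjusted p = 0.000657; adjusted p = 0.241 with an estimated correlation). Macrophage markers were not called, with 2 higher and 2 lower of 8, also adjusted over the list alone (median -0.05, adjusted p = 0.321); Cd68 rose by 0.38 ± 0.07 and Lyz2 fell by 0.89 ± 0.05.

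Genes of the sex chromosomes set the heterozygous libraries apart. Xist, the RNA that silences 1 X chromosome in female cells, was at 4.65 and 4.46 RPKM in the heterozygous libraries, at 0.0414 and 0.0479 in wild type and at 0.0209 and 0.00606 in knockout. The Y-linked gene Eif2s3y was at 0.0676 and 0.0541 RPKM in heterozygous, at 1.85 and 1.99 in wild type and at 4.95 and 5.58 in knockout. Ddx3y was at 0.133 and 0.216 RPKM in heterozygous, at 1.68 and 1.80 in wild type and at 2.88 and 2.86 in knockout, and Kdm5d had means of 0.00839, 1.21 and 2.10 RPKM. Between heterozygous and the other genotypes, genotype therefore went together with expression of Xist and loss of Y-linked transcripts. Both Y-expressing groups also differed from each other, with Eif2s3y 1.10 ± 0.06 higher in knockout on the log2 scale.

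**Figure D3:**
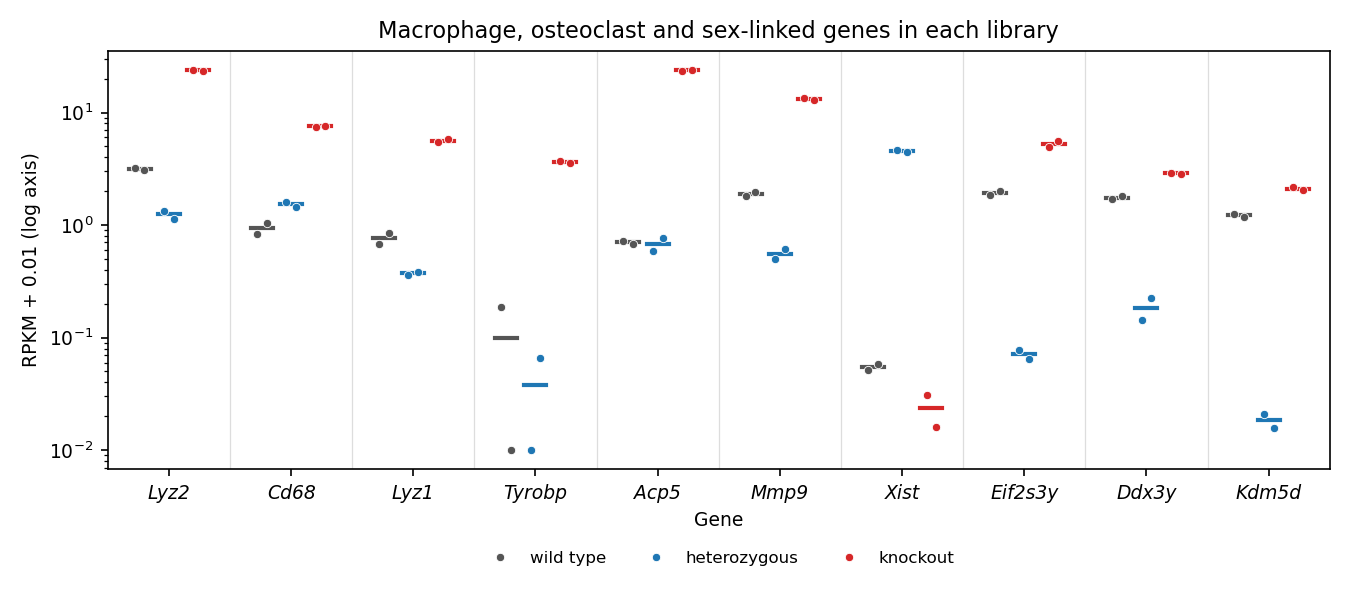
RPKM plus 0.01 on a log axis for 10 genes (x axis), with 1 point per library, 2 per genotype, and a bar at the mean of each genotype. The myeloid and osteoclast genes on the left are highest in both knockout libraries, Xist is highest in the heterozygous libraries (4.65 and 4.46 RPKM), and the Y-linked genes on the right are lowest there.

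Knockout cells differed from heterozygous ones first in genes of the monocyte lineage. Acp5 rose from 0.668 ± 0.122 RPKM in heterozygous to 23.7 ± 0.448 in knockout (SD, n = 2), Lyz2 from 1.23 ± 0.143 to 23.7 ± 0.186, Mmp9 from 0.545 ± 0.0804 to 13.1 ± 0.266, and Thbs4 from 6.37 ± 0.243 to 64.8 ± 1.79. Dlk1 rose by a log2 difference of 2.12 ± 0.05, Prg4 by 2.03 ± 0.05 and Hspb7, a small heat shock protein of muscle, by 2.05 ± 0.05. Lower in knockout were Syt13, a synaptotagmin (13 ± 0.0962 to 1.67 ± 0.00443 RPKM), and Cd59a, an inhibitor of complement (18 ± 0.331 to 4.70 ± 0.121).

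Lyz1 (2.28 ± 0.06), Tyrobp (2.17 ± 0.09) and Eif2s3y (2.56 ± 0.06) completed the largest rises. The Lyz1 row may share reads with Lyz2, which was not tested. The falls also held Xist (-2.45 ± 0.05), Gm12505 (-2.21 ± 0.09), Aldh3a1 (-1.67 ± 0.07) and 5 proliferin genes (Prl2c1 to Prl2c5, between -1.91 and -2.24) whose near-identical sequences can share reads. limma called 5644 genes, 2880 higher and 2764 lower in knockout, of which 79 changed at least 2-fold (53 higher, 26 lower). Higher calls made up 51%, against 47.4% after quantile normalization, 49.7% after median scaling and 41% (1611 higher, 2322 lower) with a filter at 5 RPKM. Camera called 6 lists, 3 upward and 3 downward. Macrophage markers (7 of 8 higher, adjusted p = 9.86e-06), cell cycle genes (20 of 26, adjusted p = 4.88e-05) and interferon response genes (11 of 11, adjusted p = 4e-05) rose. Schwann cell and neural markers (8 of 8 lower, adjusted p = 0.00024), cell cycle inhibitors (7 of 10, adjusted p = 0.0132) and X inactivation and escape genes (4 of 6, adjusted p = 0.0132) fell. Adjusted over the list alone, the counts were 7, 21, 11, 8, 7 and 4. With an estimated correlation none of the 6 held (adjusted p = 0.211, 0.211, 0.249, 0.249, 0.452 and 0.32, in that order). The call of cell cycle inhibitors was also lost after quantile normalization (adjusted p = 0.0592). Camera then called mitochondrial oxidative phosphorylation genes (adjusted p = 0.0411, against 0.125 as reported).

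Heterozygous values mostly lay between the other genotypes where those differed by at least 2-fold. Of the 278 such genes, the heterozygous mean was between wild type and knockout for 227, beyond knockout for 25 and on the other side of wild type for 26. The median heterozygous share of the knockout change was 57.0%. A preparation unrelated to both would also tend to lie between 2 that were chosen for being far apart, so these counts do not show an effect of dose. For comparison, knockout lay between for 57 of the 129 genes at least 2-fold apart in heterozygous against wild type, and wild type for 50 of the 79 in knockout against heterozygous. Mgp, Prg4, Dlk1 and H19 were intermediate, Igfbp3, Dio3, Slfn2 and Uchl1 were at the knockout level, and Acp5, Lyz2 and Tyrobp were not raised in heterozygous cells. A slope over the number of disrupted alleles was called for 4994 genes, 3209 upward and 1785 downward, and for 3065 without the first and 3146 without the second knockout library. Upward slopes made up 64.3%, against 48.0% after quantile normalization and 51.2% after median scaling. With 2 libraries at each of 0, 1 and 2 disrupted alleles, the slope equals the knockout against wild-type difference divided by 2. Heterozygous values enter only its spread, so these calls restate that difference and do not show a graded change. Acp5, not raised in heterozygous cells, was called too (limma slope 1.93, adjusted p = 0.0132).

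Both comparisons with wild type use the same 2 control libraries. They shared 2919 genes called higher and 1446 called lower, where independent lists of these sizes would share 1568 and 497. Across genes, which are not independent replicates, log2 differences had a correlation of 0.702 (0.513 in 50 simulations) and a covariance of 0.079 (0.0035 in simulations). With 1 wild-type library given to each comparison, chosen after the data were seen, 2295 were shared higher and 1160 lower (1199 and 368 for independent lists) or, the other way round, 2328 and 1180 (1212 and 380). Correlations were then 0.65 and 0.631. The lone control is assumed to vary like the other groups. Both wild-type libraries may come from the same preparation, whose traits would still enter both comparisons. The shared calls therefore cannot tell changes common to both mutant genotypes from traits of the wild-type cells.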

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

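Counts of changed genes stayed within 1.5 times of the reported ones for knockout against heterozygous and heterozygous against wild type under all alternatives but the 2-fold threshold. With adjusted p and a 2-fold threshold together, 278 genes remained in knockout against wild type, 129 in heterozygous against wild type and 79 in knockout against heterozygous. A filter at 5 RPKM, which tests fewer genes, left 4754 genes in knockout against wild type, 3138 with a slope per allele and 5 lists. Separate replicates with a 2-fold difference were found for 679 genes at a pseudocount of 0.1 and for 86 at 5, and with a 1.5-fold difference for 1259. Leaving out 1 library gave 3065 to 5153 genes with a slope, the fewest without a knockout library, where the lone sample is assumed to vary like the other groups. No list held with an estimated correlation (0 lists in place of 8). The imprinted median was -0.006 after quantile normalization, -0.047 with a filter at 5 RPKM and -0.061 for maternally expressed genes alone, and ranged from 0.03 without the second knockout library to 0.13 without the first wild-type library (0.10 without the second). The Hox median passed the threshold at 0.12 with no filter, 0.31 with a filter at 5 RPKM and 0.33 without HoxC, but was 0.04 after quantile normalization (camera p of 0.481) and 0.10 or 0.30 with a pseudocount of 5 or 0.1 (camera p of 0.105 and 0.101). Causes were not tested. For 133 differences of single named genes, 2310 alternative values were computed: 2278 kept direction and side of the threshold, 28 lost the call, 2 gained it (Hoxc11 after quantile normalization and Kdm5c after median scaling, knockout against wild type) and 2 changed sign.

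The replicate numbers did not pair the libraries: deviations of same-numbered libraries had correlations of -0.09, -0.06 and 0.07. With the number as a block, 7253, 5564 and 5448 genes were called in knockout against wild type, heterozygous against wild type and knockout against heterozygous, 4203 had a slope, and 7 lists were called. Hoxd8 turned to -0.12 after quantile normalization, and Hoxc11 ranged from -0.14 to 0.047 when 1 library was left out, with the positive value without the first wild-type library. The median of all genes moved by less than 0.1 under either scaling. Alternatives added after seeing the data gave 7487, 6056, 6083 and 4928 genes with voom and 6541, 5139, 5044 and 4476 on autosomes alone, in the same order, and a slope for 7387 genes without heterozygous libraries. DESeq2-type count tests were not run, since the values are not counts, nor was camera on HoxD alone, with 1 measured gene. At this depth Hotair and most HoxD genes stayed below the filter.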

Other observations

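Several genes of serine synthesis and amino acid stress were lower in heterozygous than in wild type and lowest in knockout. This order of cell preparations does not show an effect of dose. Psph, Psat1 and Atf4 were chosen after their values were seen, and no list of such genes was fixed or tested. The fixed heat shock and unfolded protein response list, which holds Asns, Trib3 and Chac1, was not called (4 higher and 9 lower of 16, adjusted p = 0.057). Phgdh stood at 275, 133 and 80 RPKM in wild type, heterozygous and knockout, Psph, the last enzyme of the pathway, at 26.2, 17.8 and 12.4, and Psat1, between them, at 73.2, 63.4 and 51.1. Asns, which makes asparagine, stood at 75.1, 61.4 and 42.3 RPKM, Trib3 at 12.5, 9.50 and 5.91, and Chac1 at 15.3, 13.8 and 9.41. Each fell in knockout by limma, with log2 differences from -0.51 ± 0.03 (SE, Psat1) to -1.77 ± 0.02 (Phgdh), n = 2 libraries per genotype. Atf4, the transcription factor that drives many of these genes, rose (0.17 ± 0.02).

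Single genes known from tendon were higher; Scx and Tnmd were chosen after their values were seen, and no tendon list was fixed or tested. The fixed matrix list split into 15 higher and 16 lower. Scx, the transcription factor of tendon progenitors, stood at 2.56 ± 0.0685, 5.23 ± 0.0302 and 6.44 ± 0.346 RPKM in wild type, heterozygous and knockout (SD, n = 2), and Tnmd, a membrane protein of mature tendon, at 1.92 ± 0.263, 3.80 ± 0.182 and 8.94 ± 0.647. Thbs4 and Fmod followed the same order, at 2.26, 6.37 and 64.8 RPKM and at 3.32, 9.66 and 17.4 RPKM.

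All tests below but 1 were chosen only after the result was seen; the exception is the comparison of heterozygous and knockout differences in the last paragraph, whose expected shares and split controls were added later.

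Transcripts of macrophages and osteoclasts were present in the knockout libraries: Acp5 reached 23.7 RPKM, and Atp6v0d2, a proton pump subunit of osteoclasts, rose from 0.0202 to 1.55 RPKM. A loss of fibroblasts that raised every other cell type alike is argued against by the Schwann cell and neural list (median -0.31, -0.53 after quantile normalization). That list does not measure fibroblasts, so a loss with uneven replacement was not tested. Drawing knockout reads down to the wild-type depth left the macrophage median at 1.85 (mean of 20 draws). In every draw 7 of 7 members stayed called and at least 2-fold higher. Values were already scaled to depth, so the median was bound to stay near 1.84. The draws show only that these calls do not need the extra reads. Macrophage-lineage cells are a candidate explanation, since of 13 further macrophage genes with reads 92.3% were higher in both knockout libraries than in all others (28% of all other genes with reads, 27.5% at similar levels; 84.2% of 19 in a first run, before 6 genes of the fixed lists were left out). The account has gaps, as Ctss (0.0772 to 0.445 RPKM) and Mpeg1 (0.0678 to 0.352 RPKM) were higher in knockout but stayed far below Lyz2, and Cd14 was at 1.71 and 1.97 RPKM in wild type and knockout. Loss of Hotair in the cells themselves cannot be told apart from this, because genotype goes with cell preparation and the heterozygous median of -0.05 allows a recessive effect.

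Imprinted genes at least 2-fold higher in knockout were Dlk1, H19, Dio3, Mest, Plagl1 and Dcn. Macrophage cells as their only source are argued against, since 6 of the 6 were also called higher in heterozygous libraries, against each wild-type library alone as well, although macrophage markers as a list were not raised there. The further rise from heterozygous to knockout, as in Dlk1 (2.12) and H19 (1.51), is not covered by that argument, and 174 of all 199 genes at least 2-fold higher in knockout were called higher in heterozygous too. Scaling is argued against for 5 of the 6, which stayed called and at least 2-fold higher after quantile normalization, while Plagl1 came to 0.90. Loss of Hotair (median heterozygous share of the change 58.8%, from 28.2% in Dlk1 to 98.9% in Dio3) and a difference between cell preparations cannot be told apart with these libraries.

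High Xist and low Y-linked transcripts in the heterozygous libraries would fit female cells there: the summed level of 8 Y-linked genes was 5.20% of wild type, and 4 of 4 genes known to escape X inactivation were called higher than in wild type. Of these, Kdm5c and Eif2s3x were also higher than in knockout, whereas Kdm6a and Ddx3x were as high in knockout. Wild-type libraries made of both sexes are argued against, since their Xist was 0.979% of the heterozygous level. Sex as the cause of most of the 129 genes at least 2-fold apart between heterozygous and wild type is argued against by knockout cells, which express Y-linked genes: 88.4% of those genes were called in the same direction in knockout against wild type (35.7% expected from the calls of all genes), and 83.7% or 81.1% with 1 wild-type library for each comparison (32.7% and 33.2% expected). Sex remains open for the others, such as Apol10b, which was lower in heterozygous cells alone of the 3 genotypes.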
